A study of Mus musculus with 3 samples.

How the data were processed

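Collagen gel tumours seeded with KPC cells were dissociated, frozen and thawed, and profiled by 10x Genomics droplet sequencing, per the labels' protocols. The labels' protocol text names 2 chemistries, 3' v3.1 sequenced on a NovaSeq and GEM-X 5' v3 sequenced on a Singular G4. The hashtag antibody step stands beside the first, but no file says which chemistry a library used. The submitters' processing notes name Cell Ranger 7.1.0 and 8.0.1, Seurat, mm10 and GRCm39 without saying what each was used for. The deposited matrices hold raw UMI counts per gene and barcode, unfiltered, per the files' whole-number values, with no cell annotation. They list 2161886 barcodes in set 1 and 3759224 in set 2, with 32285 genes and 3 or 4 hashtag antibodies. The files name no genome build, so only the position of Myd88 was taken from an annotation, GENCODE M21 (GRCm38), through its gene identifier. Of the gene identifiers, 32235 of 32285 were in that annotation. For the library of Col1a1CreERT2 MyD88fl/fl mice, a count matrix was not used here.

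Barcodes with at least 500 UMIs (9551 in set 1 and 15840 in set 2) were kept if they had at least 300 genes (7310 and 7872) and at most 15% mitochondrial UMIs (6238 and 4352). Droplets with 50 to 400 UMIs, taken as empty, had 27.5% mitochondrial UMIs in set 1 and 62.2% in set 2, at medians of 84 and 213 UMIs. Scrublet's own threshold marked 0 and 2 cells, so the 5% of cells with the highest score in each library (312 and 218) were removed instead, leaving 5926 and 4134. That rule was set after the scores had been seen. Cells were clustered with scanpy 1.11.5 and Leiden (leidenalg 0.10.2) at resolution 1, without the genes of the preset test lists among the features, giving 31 clusters. A cluster took the class with the most preset markers at least 2-fold above the median of the other clusters, and 28 clusters were named. This scoring replaced an earlier one (higher than in all other cells together) after the clusters had been seen. The rule that Cftr or Pkhd1 among the leading genes bars a tumour name, and Rgs5 or Notch3 a fibroblast name, was set at that point too. Names are rebuilt from markers and are written as "like" a class. Of the clusters, 5 had a low UMI count, with a median far under that of their library (3 times lower or more).

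The labels say samples were tagged with hashtag antibodies, and the tagged sample was to be the replicate if at least 2 tags per library had 200 or more singlet cells. Against the empty-droplet background, 0 tags reached that number in either library, and against the other tags' background 3 tags did in set 1 and 1 in set 2. Both ways of setting the background were chosen after the data were seen. The library was therefore the replicate (n = 2).

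UMI counts were summed per library and class, with at least 20 cells in each sum. Classes were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM, filterByExpr) in R 4.3.3, with library as a block. Each fit had 2 sums per class and 1 residual degree of freedom, so the spread is largely borrowed across genes. Classes, clusters and subclusters were formed from the same cells as were tested, so p-values between them are no independent support for the grouping. Benjamini-Hochberg adjustment was taken over all genes tested at 0.05 and also over the preset lists alone, with the second count given where it differs. The lists were MYD88 signalling, TLR and IL-1 family receptors, IL-1 family ligands and antagonist, chemokines and cytokines, MHC class I presentation, MHC class II presentation, myofibroblastic genes, inflammatory fibroblast genes, immune regulatory ligands and enzymes, T cell states and interferon response, with proliferation and dissociation stress as states for the comparison of sets. The 4 class comparisons, the lists, the limits on UMIs, genes and mitochondrial UMIs per cell, the filter on low counts and the rule for naming genes were fixed before the data were examined. The doublet rule, like the scoring of clusters and the hashtag backgrounds, was not. The rule for naming genes takes Myd88 and, from each list, up to 4 called genes with the largest fold changing the same way in both libraries, plus the most abundant uncalled member. The texts give a selection of these. Cluster 12 against fibroblast-like cells and T cell cluster 11 against 13 were added after the clusters were seen.

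The sets were compared without a test, p-value or number of changed genes. Genes with at least 20 UMIs in the class and at least a 2-fold difference were named by size, up to 4 per list. A list's median was placed among 10000 random lists of equal size matched on expression. Genes of a random list were drawn independently, while genes of a preset list can vary together, which makes extreme percentiles more frequent. Percentiles were not adjusted for the number of lists and classes, so they are descriptive and no p-values. Intervals are exact Poisson for CPM and exact binomial for shares, at 95%, and a count of 0 is given the upper limit of 3 counts. On simulated counts with 200 changed genes, the fit of fibroblast-like against tumour epithelial-like cells recovered 13% of 2-fold and 81% of 4-fold changes, that against macrophage or monocyte-like cells 78% of 2-fold and 95% of 4-fold changes, that of macrophage or monocyte-like against neutrophil-like cells 51% of 2-fold and 95% of 4-fold changes, and that of the subclusters 61% of 2-fold and 99% of 4-fold changes. For cluster 12 it was 75% of 2-fold and 95% of 4-fold changes, and for the T cell clusters 60% of 2-fold and 97% of 4-fold changes. The real fits called far more genes, which loosens the adjusted threshold, so these shares do not measure recovery on the real counts. The alternatives were DESeq2 1.42.0, no filter on low counts, no library block, at least 1000 UMIs per cell, at most 10% mitochondrial UMIs, 10% of each sum taken off as the profile of droplets with 1 to 100 UMIs, resolution 2, doublets kept and cells thinned to 1000 UMIs. Added after the data were seen were at most 25% mitochondrial UMIs, the empty-droplet profile taken off per cell, leaving out clusters of low UMI count, and a reweighting of the interferon list in which 1 set's cluster profiles were combined with the other set's cluster shares of UMIs. Also added was a limit on free RNA, the median ratio of a class's CPM to that of low-UMI droplets over markers of other classes with at least 50 UMIs there.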

Results

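The study asked what MYD88 signalling in fibroblasts does in pancreatic tumours. KPC cells, a mouse pancreatic cancer line, were implanted in collagen gels into mice in which Myd88 can be deleted from Col1a1-lineage cells by tamoxifen, or into control mice, and the dissociated tumours were profiled by droplet single-cell RNA sequencing. Of the 3 libraries, 2 came from control mice and were analysed, called set 1 and set 2. The count matrix of the library from Col1a1CreERT2 MyD88fl/fl mice was not analysed here, so no effect of the deletion is reported. Set 1 held 148793042 gene UMIs and set 2 held 104255412. After filtering, 5926 and 4134 cells remained, with medians of 5197 and 7596 UMIs per cell. The replicate was the library (n = 2), each a pool that the labels do not tie to a number of mice. With library as a block, p-values rest on how well the class difference matched between these 2 libraries and on a spread borrowed across genes. They do not measure the spread between mice.

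Myd88, the adaptor that couples Toll-like and IL-1 family receptors to NF-kB, was detected in every class of control tumour cells with a value in both sets. The gene (ENSMUSG00000032508) lies on the minus strand of chromosome 9 at 119335934 to 119341411 in GRCm38, placed by its gene identifier. Levels are means ± SD over the 2 libraries in CPM of the summed UMIs of a class. Neutrophil-like cells carried 65.9 ± 5.69 CPM, dendritic-like cells 51.9 ± 2.28 CPM and macrophage or monocyte-like cells 42.5 ± 1.81 CPM. Fibroblast-like cells carried 30.0 ± 2.74 CPM. Lower levels were measured in endothelial-like (17.5 ± 5.16 CPM), B cell-like (17.2 ± 0.953 CPM), T cell-like (15.5 ± 1.19 CPM) and tumour epithelial-like cells (12.2 ± 1.80 CPM). In edgeR's quasi-likelihood test, fibroblast-like cells exceeded tumour epithelial-like cells (log2 fold change 1.41 ± 0.28 (SE), edgeR adjusted p 0.0074). They were below macrophage or monocyte-like cells (log2 fold change -0.56 ± 0.16 (SE), edgeR adjusted p 0.019), and those were below neutrophil-like cells (log2 fold change -0.78 ± 0.24 (SE), edgeR adjusted p 0.0032). DESeq2 did not call the last pair of differences (adjusted p 0.18 and 0.11), nor did edgeR without the library block call the first of that pair (adjusted p 0.058). With each cell thinned to 1000 UMIs, dendritic-like cells (74.7 CPM) lay above neutrophil-like cells (57.1 CPM), and B cell-like cells stood at 10.7 CPM, on 4 and 1 UMIs in sets 1 and 2. The intervals of the first pair overlapped in both sets. Thinned, the order of fibroblast-like and macrophage or monocyte-like cells turned, at 42.7 and 44.4 against 42.0 and 39.6 CPM in sets 1 and 2, with overlapping intervals, so the thinned values do not rank them.

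**Figure D1:**
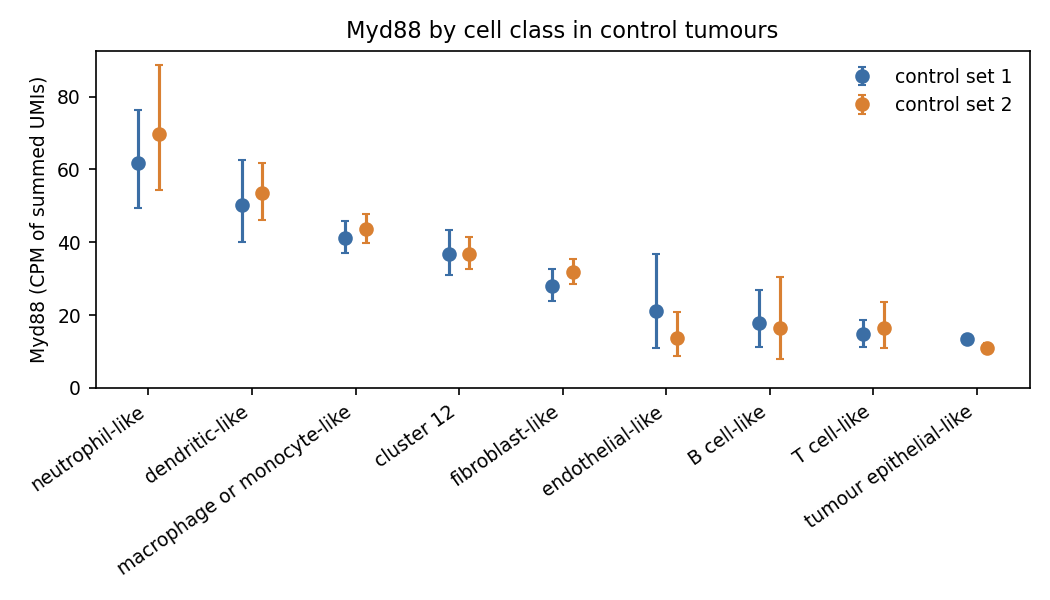
Myd88 in CPM of summed UMIs (vertical axis) by cell class (horizontal axis), 1 point per control library, with exact 95% Poisson intervals that cover counting error only. At full depth neutrophil-like cells lie at 61.8 and 69.9 CPM, and tumour epithelial-like cells at 13.4 and 10.9 CPM.

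Tumour epithelial-like and then macrophage or monocyte-like cells had the highest shares in set 1, and macrophage or monocyte-like cells the highest in set 2. Next in set 2 came fibroblast-like cells, or, with doublets kept, tumour epithelial-like (11.9%) just above fibroblast-like cells (11.7%). In that run a cluster of 76 and 141 cells with 8 fibroblast markers was barred from the fibroblast name by the rule on Rgs5. The change of order thus rests on naming. Shares are of kept cells (at least 500 UMIs, at most 15% mitochondrial UMIs), with exact 95% binomial intervals for counting error only and no test, since each set is 1 library. Tumour epithelial-like cells made up 35.8% (34.5 to 37.0) in set 1 and 11.6% (10.7 to 12.7) in set 2. Macrophage or monocyte-like cells made up 26.7% (25.6 to 27.9) in set 1 and 35.1% (33.6 to 36.6) in set 2, and fibroblast-like cells 4.40% (3.90 to 4.96) in set 1 and 14.7% (13.6 to 15.8) in set 2. Neutrophil-like cells were 9.55% (8.81 to 10.3) in set 1 and 8.90% (8.05 to 9.81) in set 2, a difference of 0.649 percentage points (-0.497 to 1.80, normal approximation). With at least 1000 UMIs per cell that difference was 1.66 (0.431 to 2.90), an interval without 0. T cell-like cells were 12.5% (11.7 to 13.4) in set 1 and 7.09% (6.32 to 7.91) in set 2, B cell-like cells 5.35% (4.79 to 5.95) in set 1 and 2.81% (2.32 to 3.36) in set 2, and dendritic-like cells 2.48% (2.10 to 2.91) in set 1 and 7.76% (6.97 to 8.62) in set 2. At up to 25% mitochondrial UMIs, with cells clustered again, dendritic-like cells were 1.18% and 3.30%, a difference of -2.12 points against -5.28. A cluster of 80 and 210 cells there, with 5 dendritic and 5 macrophage or monocyte markers, went unnamed by that tie. It carried the same 5 dendritic markers as main cluster 14 (82 and 180 cells), which was named dendritic-like. The smaller difference is thus partly one of naming. Endothelial-like cells were 0.624% (0.440 to 0.860) in set 1 and 3.53% (2.99 to 4.14) in set 2. Acinar-like cells were 0.135% (0.0583 to 0.266) in set 1 and 0.460% (0.277 to 0.717) in set 2. For acinar-like cells the interval of the difference held 0 at up to 10% mitochondrial UMIs (-0.367 to 0.0506), and the difference of -0.325 points became -0.581 at resolution 2 and -0.510 at up to 25%. Plasma cell-like cells were 0.314% of set 2 and 0 of 5926 cells in set 1, which allows a share of up to 0.0506% by the limit of 3 counts for a count of 0, where the exact interval would reach 0.0622%. That 0 depends on the filters and the clustering, as set 1 had 25 such cells with doublets kept (0.401%) and 22 at up to 25% mitochondrial UMIs (0.351%).

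**Figure D2:**
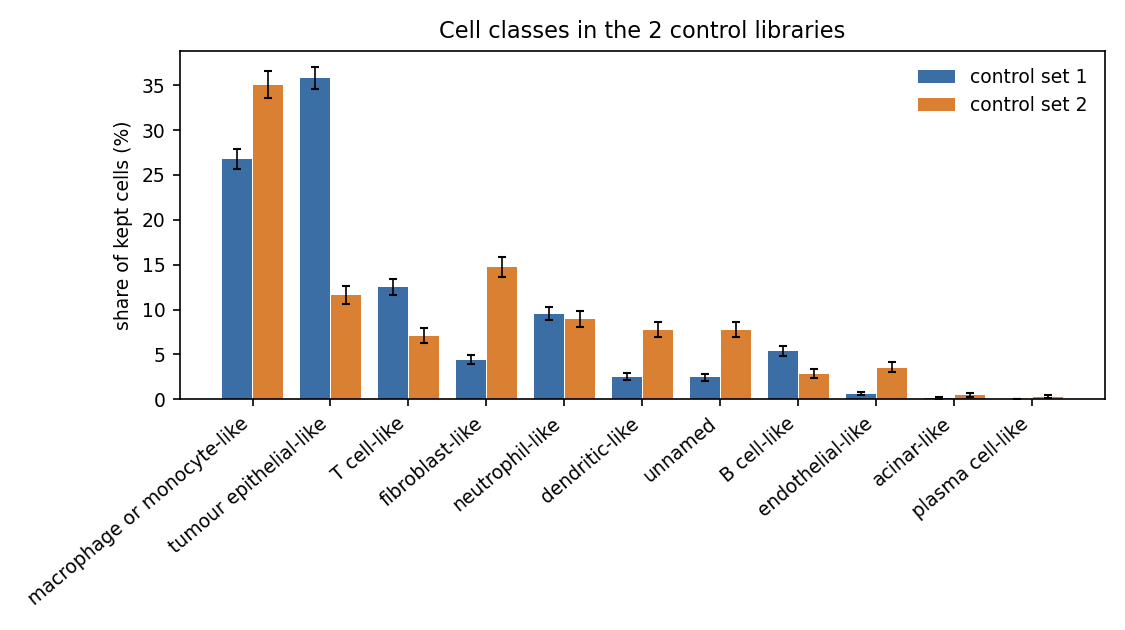
Share of kept cells in percent (vertical axis) by cell class (horizontal axis) in the 2 control libraries, with exact 95% binomial intervals. Tumour epithelial-like cells are 35.8% of set 1 and 11.6% of set 2.

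Tumour epithelial-like, macrophage or monocyte-like and T cell-like cells were spread differently over their clusters in the 2 sets, while cluster 3 held most neutrophil-like cells (471 of 566 and 309 of 368) and cluster 6 most fibroblast-like cells (203 of 261 and 455 of 608) in both. The clusters with the most tumour epithelial-like cells of set 1 were 1 (723 cells, of low UMI count) and 5 (648 cells), and those of set 2 were 8 (200 cells) and 1 (110 cells). For macrophage or monocyte-like cells it was cluster 0 in set 1 (652 of 1585 cells, of low UMI count) and cluster 2 in set 2 (570 of 1450 cells). T cell-like cells of set 1 lay mainly in clusters 13 (278 cells, with Cd8a), 11 (238 cells, with Cd4) and 15 (177 cells, with Cd8a), and those of set 2 in clusters 11 (161 cells), 15 (73 cells) and 13 (50 cells). Cluster 15 carried 7 T cell markers and 6 NK cell markers, the latter Ncr1, Klrb1c, Klre1, Gzma, Eomes and Klrk1. Median mitochondrial content of kept cells was 3.54% in set 1 and 6.86% in set 2. Within the fibroblast-like class, a subcluster of 8 and 80 cells was led by Krt8, Krt18 and Krt7, and another of 0 and 11 cells by the pericyte genes Rgs5 and Notch3. Clusters 12, 23 and 25 were left unnamed. Cluster 12 carried mesothelial beside fibroblast markers and made up 2.19% (1.84 to 2.60) of set 1 and 5.85% (5.16 to 6.61) of set 2. Cluster 23, led by Cp and Pkhd1 and with 7 tumour epithelial markers, was kept out of the tumour epithelial-like class by a rule set after the clusters were seen, and made up 0.101% and 1.26%, and cluster 25, with dendritic and plasma cell markers, 0.152% and 0.605%.

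Most matrix and inflammatory fibroblast genes were higher in fibroblast-like than in tumour epithelial-like cells, the MHC class II genes were lower, and chemokines and receptors went both ways. Periostin (Postn), a matrix protein, was measured at 662 ± 34.0 against 0.788 ± 0.000318 CPM (log2 fold change 9.78 ± 0.41 (SE), edgeR adjusted p 2.0e-05). Of the myofibroblastic genes, 15 of 16 were higher and 0 lower, and of the inflammatory fibroblast genes, 14 of 16 were higher and 0 lower (15 and 0 adjusted over the list alone). Ogn (10.13 ± 0.43), Igf1 (9.49 ± 0.49), Tnc (9.48 ± 0.71) and Tagln (9.43 ± 0.44) were among them. Single values in parentheses here and for the other class comparisons are log2 fold changes ± SE, and CPM are means ± SD (n = 2). Of the chemokines and cytokines, 15 of 26 were higher and 2 lower. Cxcl12, which attracts CXCR4-bearing leukocytes, stood at 365 ± 76.4 against 0.885 ± 0.519 CPM, the eosinophil chemokine Ccl11 at 236 ± 52.0 against 0.446 ± 0.157 CPM, and Il6 at 903 ± 191 against 2.86 ± 1.86 CPM. Inhba at 135 ± 82.1 against 93.2 ± 53.1 CPM did not pass the test (edgeR adjusted p 0.36).

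Of the TLR and IL-1 family receptors, 8 of 14 were higher and 3 lower. The IL-36 receptor gene Il1rl2 (46.9 ± 16.7 against 0.192 ± 0.0571 CPM) and the IL-33 receptor gene Il1rl1 (37.4 ± 7.46 against 0.261 ± 0.156 CPM) were higher in fibroblast-like cells, and Il18rap, part of the IL-18 receptor, was lower (1.81 ± 0.611 against 36.1 ± 13.2 CPM). Of the MYD88 signalling genes, 4 of 17 were higher and 5 lower. Irak3, an inhibitory member of the IRAK family, was higher (log2 fold change 5.62 ± 0.43 (SE), edgeR adjusted p 0.00013), as was Nfkb1 (3.24 ± 0.43), while Irak2 (-1.50 ± 0.22) and Ikbkg (-1.59 ± 0.25) were lower. The 5 lower became 3 with DESeq2, without the library block and with 10% taken off as free RNA. Of the IL-1 family ligands and antagonists, 1 of 7 were higher and 3 lower. Il33 was higher (322 ± 59.7 against 120 ± 15.9 CPM) and the antagonist gene Il1rn lower (8.11 ± 5.15 against 116 ± 30.8 CPM). DESeq2 did not call the lower levels of Il1a and Il18 (adjusted p 0.095 and 0.11).

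Tumour epithelial-like cells exceeded fibroblast-like cells in MHC class II genes and in some class I genes. Among the MHC class II presentation genes, 0 of 7 were higher and 7 lower, with the invariant chain gene Cd74 at 69.2 ± 25.6 against 338 ± 1.06 CPM. Of the MHC class I presentation genes, 0 of 10 were higher and 4 lower, among them Nlrc5 (-1.61 ± 0.31) and the immunoproteasome gene Psmb9 (-1.31 ± 0.27). With 10% taken off as free RNA, 2 class I genes were called (0 adjusted over the list alone), and without the library block 4 (1 adjusted over the list alone). Calls rose to 6 with no filter on low counts (7 adjusted over the list alone) and to 5 without the clusters of low UMI count (6 adjusted over the list alone). H2-K1 at 666 ± 32.8 against 1481 ± 574 CPM did not pass (edgeR adjusted p 0.098), though it did with DESeq2 (adjusted p 0.020). Of the immune regulatory ligands and enzymes, 4 of 15 were higher and 3 lower, with Ido1, which degrades tryptophan, lower (1.51 ± 0.292 against 74.1 ± 54.2 CPM) and Tgfb2 higher (232 ± 84.3 against 8.22 ± 2.08 CPM). Of the interferon response genes, 5 of 14 were higher and 2 lower, with Isg15 higher (2.14 ± 0.23) and Gbp2 lower (-2.19 ± 0.52). Without the library block 2 of the interferon response genes were called higher. With 10% taken off as free RNA, 0 of them were called lower, 2 immune regulatory genes higher and 1 T cell states gene higher. With no filter on low counts 5 immune regulatory (6 adjusted over the list alone) and 4 T cell states genes were lower. Isg15 lost its call without the library block (edgeR adjusted p 0.052) and Gbp2 with 10% taken off as free RNA (edgeR adjusted p 0.086). Of the T cell states genes, 2 of 9 were higher and 2 lower, with Lag3 at 9.12 ± 1.22 against 2.99 ± 0.0940 CPM and Havcr2 at 0.631 ± 0.163 against 13.7 ± 6.69 CPM. Over all genes, edgeR called 3914 higher and 3525 lower in fibroblast-like cells among 15312. On simulated counts this fit recovered 13% of 2-fold and 81% of 4-fold changes. Free RNA can put a floor under the lower value and so limit such folds: Col1a1 stood at 10722 and 8513 CPM in fibroblast-like cells and at 16.9 and 22.2 CPM in tumour epithelial-like cells. With 10% of each sum taken off as free RNA, the genes lower in fibroblast-like cells numbered 2278.

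Fibroblast-like and macrophage or monocyte-like cells divided the inflammatory mediators between them. Fibroblast-like cells carried Il33 (322 ± 59.7 against 3.34 ± 0.451 CPM), Ccl11 (236 ± 52.0 against 0.799 ± 0.295 CPM) and Cxcl12 (365 ± 76.4 against 1.81 ± 1.72 CPM), and macrophage or monocyte-like cells carried Il1b (31.1 ± 10.2 against 4351 ± 384 CPM), Il1a (2.64 ± 0.0892 against 304 ± 132 CPM) and Ccl4 (6.37 ± 2.20 against 535 ± 55.7 CPM). Il1b differed by a log2 fold change of -7.20 ± 0.27 (SE, edgeR adjusted p 5.5e-07). Of the chemokines and cytokines, 13 of 26 were higher and 11 lower in fibroblast-like cells, and of the IL-1 family ligands and antagonists, 2 of 7 were higher and 5 lower. Of the TLR and IL-1 family receptors, 4 of 18 were higher and 13 lower. The lipopolysaccharide co-receptor gene Cd14 (8.90 ± 0.310 against 1260 ± 220 CPM) was lower, and Tlr8 had 0 UMIs in fibroblast-like and 180 in macrophage or monocyte-like cells. Tlr3 at 8.84 ± 2.28 against 8.04 ± 1.19 CPM did not pass the test. Of the MYD88 signalling genes, 1 of 17 were higher and 7 lower, with Irak2 (-4.56 ± 0.20), Traf6 (-2.81 ± 0.19) and Irak4 (-1.35 ± 0.18) lower in log2 fold change.

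Antigen presentation genes were lower in fibroblast-like than in macrophage or monocyte-like cells. Of the MHC class I presentation genes, 0 of 10 were higher and 10 lower, with Tap1 at 27.8 ± 0.402 against 102 ± 0.212 CPM, and of the MHC class II presentation genes, 0 of 7 were higher and 7 lower, with H2-Aa at 27.8 ± 11.2 against 3662 ± 679 CPM. Of the immune regulatory ligands and enzymes, 2 of 16 were higher and 11 lower. The costimulatory gene Cd86 (3.13 ± 1.51 against 1448 ± 43.3 CPM) and Arg1, the arginine-degrading enzyme (10.5 ± 0.798 against 1146 ± 48.1 CPM), were lower, and Spp1 at 2110 ± 2164 against 770 ± 8.90 CPM did not pass the test. Of the myofibroblastic genes, 15 of 16 were higher and 1 lower, and of the inflammatory fibroblast genes, 14 of 16 were higher and 2 lower, with Col8a1 (9.46 ± 0.27) and Has1 (7.80 ± 0.25) higher. Of the interferon response genes, 1 of 14 were higher and 5 lower (1 and 4 adjusted over the list alone), and of the T cell states genes, 5 of 9 were higher and 3 lower, with 1 higher by DESeq2 and 3 (4 adjusted over the list alone) with 10% taken off as free RNA. The interferon response genes lower were 3 with 10% taken off and 9 with no filter on low counts, and DESeq2 called 0 higher. Without the library block 0 myofibroblastic genes were lower and 1 IL-1 family and 0 MYD88 signalling genes higher. Over all genes, edgeR called 4617 higher and 3924 lower among 14122.

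Neutrophil-like cells carried the highest IL-1 transcript levels of the myeloid pair, and macrophage or monocyte-like cells the MHC class II genes. Il1b stood at 4351 ± 384 against 14611 ± 1779 CPM in macrophage or monocyte-like against neutrophil-like cells (log2 fold change -1.90 ± 0.38 (SE), edgeR adjusted p 5.3e-06), Il1a at 304 ± 132 against 1453 ± 18.2 CPM and Il1rn at 610 ± 3.95 against 2126 ± 403 CPM. Of the IL-1 family ligands and antagonists, 1 of 7 were higher and 4 lower in macrophage or monocyte-like cells. The decoy receptor gene Il1r2 (393 ± 58.3 against 5500 ± 223 CPM) and Il18rap (7.32 ± 4.01 against 207 ± 10.7 CPM) were lower there, and of the TLR and IL-1 family receptors, 6 of 18 were higher and 8 lower. Of the MYD88 signalling genes, 1 of 17 were higher and 6 lower, with Tirap (-2.12 ± 0.34), Irak3 (-1.96 ± 0.24) and Nfkbia (-1.67 ± 0.30) lower. Of the chemokines and cytokines, 11 of 24 were higher and 9 lower. Cxcl9 (382 ± 178 against 16.1 ± 5.35 CPM) and Cxcl16 (309 ± 84.2 against 13.4 ± 2.86 CPM) were higher, and Lcn2, an iron-scavenging granule protein (4.67 ± 3.75 against 719 ± 269 CPM), and Csf1 (12.8 ± 5.87 against 525 ± 156 CPM) were lower.

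Among the MHC class II presentation genes, 7 of 7 were higher and 0 lower in macrophage or monocyte-like cells, with H2-Aa at 3662 ± 679 against 66.2 ± 24.2 CPM, and of the MHC class I presentation genes, 1 of 10 were higher and 1 lower (0 and 0 adjusted over the list alone). Of the interferon response genes, 2 of 14 were higher and 9 lower (2 and 10 adjusted over the list alone), with Rsad2 (52.3 ± 32.5 against 365 ± 6.99 CPM) and Ifit1 (14.9 ± 3.68 against 89.6 ± 22.1 CPM) lower. Of the immune regulatory ligands and enzymes, 5 of 16 were higher and 4 lower, with Arg1 (1146 ± 48.1 against 14.1 ± 1.85 CPM) and Il10 (65.3 ± 4.88 against 5.41 ± 0.387 CPM) higher. Of the myofibroblastic genes, 1 of 11 were higher and 5 lower, of the inflammatory fibroblast genes, 5 of 13 were higher and 3 lower, and of the T cell states genes, 4 of 6 were higher and 1 lower. The 5 lower myofibroblastic calls became 0 with DESeq2, 1 without the library block and 0 with 10% taken off as free RNA, where 2 of these genes were still measured. With DESeq2, 1 of the T cell states genes and 3 of the receptors were higher, with 1 interferon response gene and 0 MHC class I, IL-1 family and MYD88 signalling genes. Adjusted over the list alone, those were 4 receptors, 2 interferon response genes and 1 IL-1 family gene, with the others as over all genes. Without the library block 2 T cell states genes (4 adjusted over the list alone), 1 interferon response gene (2) and 0 MHC class I genes were higher, and neither alternative called a class I gene lower. Over all genes, edgeR called 2769 higher and 2267 lower among 11587, and DESeq2 called 1225 and 1275.

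The 2 largest fibroblast-like subclusters, separated without the genes of the preset lists, differed in inflammatory against myofibroblastic genes. The split and the test used the same cells, so list genes that vary with the genes used for clustering differ by construction. The p-values and counts therefore describe the split and are no independent support for it, and the counts over all genes include the clustering genes. Subcluster 1 (79 and 174 cells in sets 1 and 2), led by Opcml, Sfrp4, Cxcl13 and Dpt, carried more of the inflammatory fibroblast genes: 14 of 16 were higher and 1 lower (15 and 1 adjusted over the list alone). Clec3b stood at 476 ± 86.1 against 14.1 ± 11.2 CPM in subcluster 1 against subcluster 2 (log2 fold change 5.23 ± 0.31 (SE), edgeR adjusted p 9.0e-05), Ly6c1 at 505 ± 110 against 34.5 ± 0.793 CPM and Ly6a differed by a log2 fold change of 2.53 ± 0.15. Subcluster 2 (83 and 98 cells), led by Thbs4 and Ltbp2, carried more of the myofibroblastic genes, of which 0 of 16 were higher and 10 lower in subcluster 1. Smooth muscle actin (Acta2) stood at 184 ± 36.9 against 1190 ± 259 CPM (log2 fold change -2.60 ± 0.15 (SE), edgeR adjusted p 9.0e-05), Col11a1 at 0.758 ± 0.374 against 119 ± 35.4 CPM and Inhba at 24.1 ± 3.66 against 249 ± 78.9 CPM. Sparc at 10368 ± 3723 against 11005 ± 1434 CPM did not pass the test.

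Of the chemokines and cytokines, 11 of 23 were higher and 2 lower (13 and 2 adjusted over the list alone) in subcluster 1, with Cxcl5 at 123 ± 0.460 against 20.9 ± 0.132 CPM and Cxcl12 at 655 ± 134 against 135 ± 99.9 CPM. DESeq2 did not call Cxcl12 (adjusted p 0.068). Of the MYD88 signalling genes, 2 of 17 were higher and 0 lower (3 and 0 adjusted over the list alone), with Irak3 at 132 ± 21.4 against 24.7 ± 0.130 CPM and Nfkbia (0.96 ± 0.16). Myd88 stood at 29.2 ± 2.15 against 25.2 ± 3.47 CPM and did not pass (log2 fold change 0.28 ± 0.21 (SE), edgeR adjusted p 0.51). Of the TLR and IL-1 family receptors, 2 of 10 were higher and 0 lower (7 and 0 adjusted over the list alone), with Il1rl1 at 47.0 ± 10.2 against 15.7 ± 6.97 CPM. Of the MHC class I presentation genes, 3 of 10 were higher and 0 lower, among them H2-K1 (0.85 ± 0.14). For the MHC class II presentation genes, 0 of 6 were higher and 0 lower, with Cd74 at 44.2 ± 2.53 against 30.4 ± 7.52 CPM. Counts for the other lists were 1 higher and 4 lower of 12 (2 and 6 adjusted over the list alone) for immune regulatory ligands and enzymes, 0 higher and 3 lower of 5 for T cell states, 1 higher and 0 lower of 14 for interferon response and 1 higher and 0 lower of 6 for IL-1 family ligands and antagonists. Tgfb1 (59.7 ± 24.0 against 218 ± 46.2 CPM) was lower in subcluster 1. Over all genes, edgeR called 726 higher and 538 lower among 11163, and 178 and 181 without the library as a block. Without it, edgeR no longer called Cxcl12, Il1rl1, H2-K1 or Nfkbia (adjusted p 0.068, 0.064, 0.13 and 0.20). It called 9 inflammatory fibroblast genes, 5 chemokines and cytokines and 1 MYD88 signalling gene higher and 0 in the receptor, MHC class I, interferon response, IL-1 family and immune regulatory lists, and lower 6 myofibroblastic, 2 immune regulatory, 1 T cell states, 1 chemokine and 0 inflammatory fibroblast genes. Adjusted over the list alone, the fit without the block called 15 inflammatory fibroblast genes, 12 chemokines and cytokines, 5 receptors and 1 immune regulatory gene higher, and 10 myofibroblastic, 4 immune regulatory and 2 T cell states genes lower, with its other counts as over all genes. DESeq2 called 0 IL-1 family and immune regulatory genes higher and 0 T cell states, chemokine and inflammatory fibroblast genes lower (2 chemokines and 1 inflammatory fibroblast gene adjusted over the list alone), and with no filter on low counts edgeR called 6 receptors (8 adjusted over the list alone) and 4 MYD88 signalling genes higher and 4 chemokines lower.

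**Figure D3:**
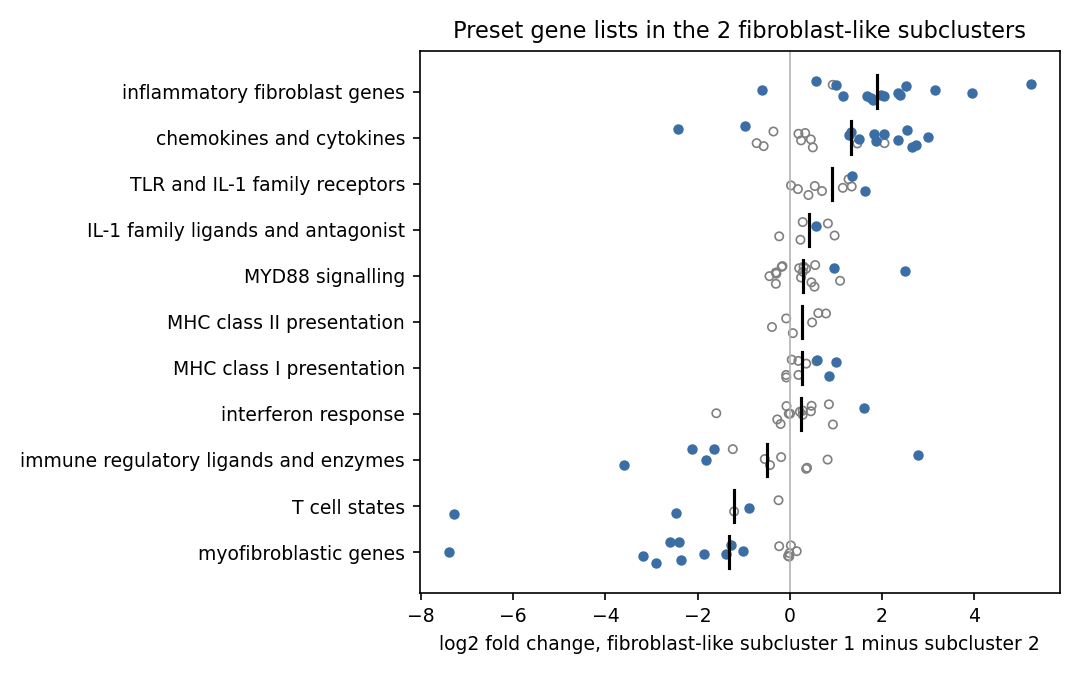
Log2 fold change of fibroblast-like subcluster 1 minus subcluster 2 (horizontal axis) for the genes of each preset list (vertical axis). Filled points passed edgeR's adjusted p of 0.05, open points did not, and the black line is the list's median. Lef1, among the T cell states, had 0 UMIs in subcluster 1 and is drawn at its fitted value, which is no bound, and the medians run from -1.33 for myofibroblastic genes to 1.90 for inflammatory fibroblast genes.

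Between the control sets, the median of the interferon response genes was lower in set 2 in tumour epithelial-like, macrophage or monocyte-like and neutrophil-like cells, and Isg15, the ubiquitin-like interferon-induced gene, was lower in all 6 classes compared. No test was possible, as each set is 1 library, and set cannot be told apart from library run, so values with exact 95% Poisson intervals describe these libraries only. The list's median log2 ratio of set 2 over set 1 was -1.11 in tumour epithelial-like, -0.88 in macrophage or monocyte-like and -0.77 in neutrophil-like cells. Each lay at percentile 0 among 10000 random lists matched on expression, a descriptive placement that does not allow for list genes varying together. It was -0.03 in fibroblast-like, 0.02 in T cell-like and -0.13 in dendritic-like cells, at percentiles 22.0, 32.6 and 7.54. The median over all genes was 0.32 in tumour epithelial-like and 0.08 in macrophage or monocyte-like cells. Isg15 in neutrophil-like cells stood at 862 CPM (814 to 911) in set 1 and 136 CPM (114 to 161) in set 2, and in macrophage or monocyte-like cells at 228 CPM (218 to 238) in set 1 and 55.2 CPM (50.9 to 59.8) in set 2. In the other classes Isg15 stood at 152 CPM (133 to 172) and 48.5 CPM (41.6 to 56.3) in dendritic-like, 168 CPM (158 to 179) and 58.0 CPM (53.6 to 62.8) in fibroblast-like and 42.9 CPM (37.0 to 49.5) and 15.2 CPM (9.93 to 22.3) in T cell-like cells of sets 1 and 2, while Rsad2 in fibroblast-like cells went the other way, from 3.44 CPM (2.10 to 5.31) to 15.0 CPM (12.8 to 17.5). Cxcl10 in tumour epithelial-like cells stood at 118 CPM (116 to 121) in set 1 and 24.9 CPM (22.8 to 27.1) in set 2. With 10% taken off as free RNA, the log2 ratio of Cxcl10 went from -2.25 to -3.04. The MHC class I presentation list had a median of -0.70 in tumour epithelial-like cells (percentile 0.18), with H2-D1 at 1212 CPM (1205 to 1219) in set 1 and 530 CPM (521 to 540) in set 2. This class was made up differently in the sets: cluster 5 held 50.4% of its UMIs in set 1 and 5.82% in set 2, and cluster 8 19.2% and 50.2%. Makeup was not tested for the class I list.

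**Figure D4:**
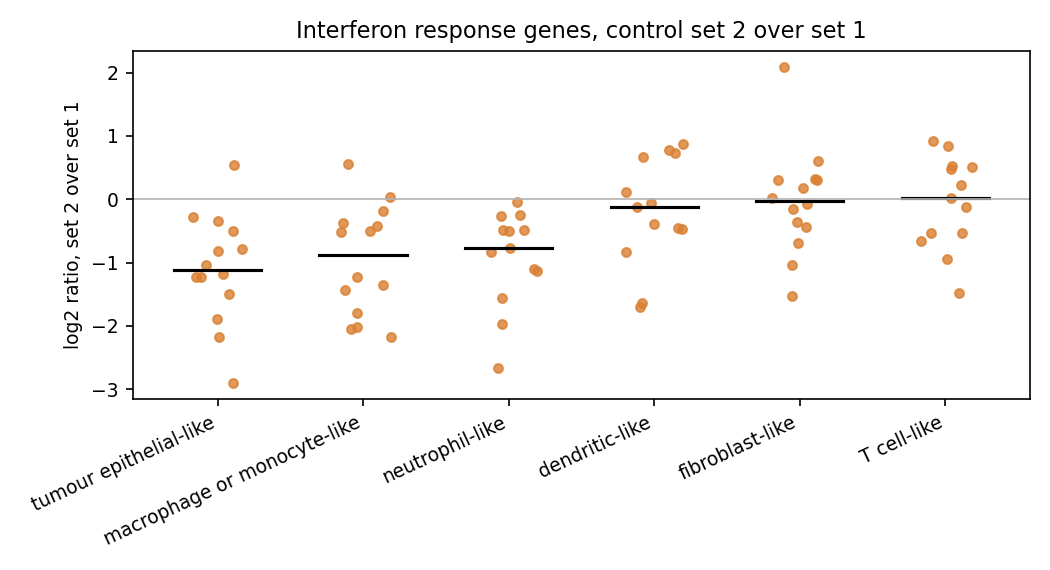
Log2 ratio of set 2 over set 1 (vertical axis) for interferon response genes in 6 cell classes (horizontal axis), 1 point per gene with at least 20 UMIs and black lines at the medians. The medians lie at -1.11, -0.88 and -0.77 in the first 3 classes.

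Other lists also differed between the sets. In fibroblast-like cells the median of the inflammatory fibroblast genes was 0.61 (percentile 100), with Gsn at 517 CPM (499 to 536) in set 1 and 1302 CPM (1280 to 1323) in set 2, and that of the TLR and IL-1 family receptors 0.46 (percentile 99.2). The class was made up differently in the 2 sets: subcluster 2, in which 14 of 16 inflammatory fibroblast genes were lower than in subcluster 1, was 31.8% of it in set 1 and 16.1% in set 2, and subcluster 3 was 8.81% and 22.7%. The inflammatory fibroblast list was also higher in set 2 in tumour epithelial-like (median 0.83, percentile 99.45), T cell-like (0.74, 99.89) and neutrophil-like cells (0.42, 96.68). So were the receptors in tumour epithelial-like (0.87, 98.75) and T cell-like cells (0.60, 99.76). Myofibroblastic genes had 2.47 (percentile 100) in dendritic-like cells. Col1a1 in empty droplets stood at 468 and 741 CPM in sets 1 and 2. Free RNA was not tested for these lists. Spp1 in fibroblast-like cells stood at 3641 CPM (3592 to 3690) in set 1 and 580 CPM (565 to 594) in set 2. In T cell-like cells, of which clusters 13, 11 and the NK-marked 15 held 278, 238 and 177 cells in set 1 and 50, 161 and 73 in set 2, Ifng, the effector cytokine, stood at 216 CPM (203 to 231) in set 1 and 46.2 CPM (36.6 to 57.6) in set 2, and Foxp3, the regulatory T cell factor, at 34.3 CPM (29.1 to 40.3) in set 1 and 115 CPM (99.6 to 132) in set 2. Ccl8 in macrophage or monocyte-like cells stood at 450 CPM (436 to 465) in set 1 and 83.1 CPM (77.8 to 88.7) in set 2. The proliferation list had medians of -1.23 in macrophage or monocyte-like, -1.32 in dendritic-like and -0.63 in fibroblast-like cells, each at percentile 0, against 0.29 in tumour epithelial-like cells (percentile 54.4). The dissociation stress list had a median of 0.32 in neutrophil-like cells (percentile 99.9), 0.25 in fibroblast-like cells (percentile 98.0) and -0.32 in tumour epithelial-like cells (percentile 44.3).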

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

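The hashtag counts, which enter no comparison of the report, were to assign cells to samples, but too few cells stood apart from empty droplets for that. The level used here, the 99th percentile of empty droplets, was chosen after the data were seen. They stood out because some cells carried more of a tag than 99% of empty droplets did, which chance alone gives to 1% of droplets. In set 1 the share of cells above that level was 1.37% (1.09 to 1.70) for hashtag 6, 2.63% (2.24 to 3.07) for hashtag 7 and 1.37% (1.09 to 1.70) for hashtag 8. In set 2 it was 1.45% (1.11 to 1.86) for hashtag 6, 1.74% (1.37 to 2.19) for hashtag 7, 1.48% (1.13 to 1.89) for hashtag 8 and 3.07% (2.57 to 3.64) for hashtag 9, with exact binomial intervals. Any tag was above it in 5.30% of set 1 and 6.31% of set 2 cells. Median tag counts were nearly equal in cells and empty droplets, for example 1125 and 1102 for hashtag 8 in set 1, and 11041 and 10864 for hashtag 9 in set 2.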

How the results depend on the processing

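The doublet rule, the limit of 25% mitochondrial UMIs, the empty-droplet profile, leaving out clusters of low UMI count and the 2 comparisons of cluster 12 and of T cell clusters 11 and 13 were chosen after the data were seen. Over the genes the naming rule took and the alternatives other than each library alone, 1722 values of called genes kept direction and call and 108 kept direction and lost the call. Genes without a value under an alternative are left out of these counts and are not counted as lost. With 10% taken off as free RNA, 38 of 43 named genes of the T cell clusters and 35 of 40 of the subclusters had a value. Of uncalled genes, 31 values gained it and 11 changed direction without one. Each library alone has no test and the rule fixes its direction for called genes, so it adds nothing for them, and 19 such values of uncalled genes had the other direction. Thinned to 1000 UMIs, Myd88 in fibroblast-like cells lay above that in macrophage or monocyte-like cells, the other order from unthinned sums, within counting error. The cause of the changes below was not tested, except where the alternative's own floor sets a value or a cluster is said to have lost its name. Without the library as a replicate block, subcluster 1 against 2 gave 15 higher and 10 lower list genes against 35 and 20, and 178 and 181 over all genes. Without that block, cluster 12 gave 23 and 24 list genes and 656 and 694 over all, and the T cell clusters 21 and 4 and 596 and 208. DESeq2 gave 1225 and 1275 for macrophage or monocyte-like against neutrophil-like cells, 328 and 246 for the subclusters (13 lower list genes), 831 and 929 for cluster 12, and 412 and 177 for the T cell clusters (5 lower list genes). With no filter on low counts the subclusters gave 1113 and 844, and cluster 12 2278 lower. With 10% taken off as free RNA, 2278 genes were lower in fibroblast-like than in tumour epithelial-like cells.

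Differences in share, set 1 minus set 2 in percentage points, moved as follows. At most 10% mitochondrial UMIs gave 3.34 for B cell-like and -6.48 for dendritic-like cells. At most 25% gave -2.12 for dendritic-like, -0.0619 for plasma cell-like and 22.3 for tumour epithelial-like cells. For dendritic-like cells part of that is naming, as a cluster of 80 and 210 cells with tied dendritic and macrophage or monocyte markers went unnamed. At least 1000 UMIs gave 6.99 for T cell-like and -11.8 for macrophage or monocyte-like cells. Resolution 2 gave -0.581 for acinar-like cells, and keeping doublets -8.04 for fibroblast-like cells. With doublets kept, a cluster of 76 and 141 cells with 8 fibroblast markers lost that name by the rule on Rgs5, which lowers this class. The neutrophil-like difference became 1.66 with at least 1000 UMIs, where its interval left 0, and the acinar-like one -0.158 at up to 10% mitochondrial UMIs, where its interval took in 0. Myd88 in CPM moved by more than 1 SD with cells thinned to 1000 UMIs, to 10.7 in B cell-like, 74.7 in dendritic-like, 43.6 in fibroblast-like and 57.1 in neutrophil-like cells. Cells under 1000 UMIs were left out, and few Myd88 UMIs remained, 4 and 1 in B cell-like and 10 and 26 in fibroblast-like cells of sets 1 and 2. In these classes each library's interval held its unthinned value, so these moves lie within counting error. Thinned, the mean was highest in dendritic-like rather than neutrophil-like cells, with overlapping intervals in both sets. With 10% taken off as free RNA Myd88 was 38.5 in cluster 12, 55.2 in dendritic-like and 44.7 in macrophage or monocyte-like cells, and with the empty-droplet profile 36.9 in cluster 12. The main value of cluster 12 was 36.8 ± 0.0488 CPM, so 36.9 lies past 1 SD only because that SD is so small.

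Of the 121 differences named between the sets, 72 had UMIs left in both sets with 10% taken off as free RNA. Of these, 57 stayed inside their intervals, 14 moved outside and kept their sign, and 1 changed it, Ccl8 in tumour epithelial-like cells (log2 ratio 0.33). For the other 49, 0 UMIs were left in 1 set (20) or in both (29), so the size of the value, and with 0 in both sets also its sign, is set by the alternative's own floor and tests nothing. With 0 in both sets, 11 values had the other sign: -1.13 for Inhba, Tagln, Tnc and Saa3 in dendritic-like cells, -0.36 for Cxcl12, Has1, Col5a1, Postn and Lox in macrophage or monocyte-like cells, 2.10 for Ifng in tumour epithelial-like cells and -0.88 for Il1rn in fibroblast-like cells. With the empty-droplet profile 1 value moved. Not run were tagged samples as replicates, each left out in turn, and the tag ratio call, since tags assigned too few cells, and DESeq2 or no filter between sets, where there is no test.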

Other observations

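The comparisons of cluster 12 and of the T cell clusters, the tests of low-UMI droplets, free RNA, cluster makeup and Y-linked RNA, and the choice of the interferon pattern, weighed in place of the hashtag counts, were made after the values had been seen. Cluster 12 and the T cell clusters were formed from the same cells as were tested, so their p-values are no independent support for the grouping. The tests of the mitochondrial filter and of nuclear RNA were set before their own values were seen, the first of them after shares at 25% mitochondrial UMIs were known.

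Cluster 12 (130 and 242 cells), in which mesothelial markers such as Upk3b, Lrrn4 and Wt1 stood beside Col1a1 and Dcn, carried more antigen presentation transcripts than fibroblast-like cells. Of the MHC class II presentation genes, 6 of 7 were higher and 0 lower (7 and 0 adjusted over the list alone), with Cd74 at 1335 ± 5.23 against 69.2 ± 25.6 CPM (log2 fold change 4.21 ± 0.22 (SE), edgeR adjusted p 0.00021), and of the MHC class I presentation genes, 9 of 10 were higher and 0 lower, with H2-K1 at 1866 ± 415 against 666 ± 32.8 CPM. Of the interferon response genes, 8 of 14 were higher and 0 lower (10 and 0 adjusted over the list alone), with Oasl2 at 238 ± 88.2 against 49.2 ± 0.563 CPM. The acute-phase gene Saa3 (3610 ± 1693 against 596 ± 112 CPM) was higher, and of the chemokines and cytokines, 6 of 26 were higher and 8 lower, with Ccl11 lower (1.43 ± 0.551 against 236 ± 52.0 CPM). The IL-18 receptor gene Il18r1 (36.2 ± 13.8 against 3.83 ± 0.790 CPM) and Il18 (22.4 ± 7.08 against 4.27 ± 0.766 CPM) were higher, in lists where 5 higher and 1 lower of 13 (6 and 2 adjusted over the list alone) of the receptors and 2 higher and 1 lower of 7 of the ligands were called. Of the inflammatory fibroblast genes, 0 of 16 were higher and 14 lower, with Pi16 at 13.7 ± 3.22 against 412 ± 79.5 CPM, and of the myofibroblastic genes, 1 of 16 were higher and 13 lower (1 and 14 adjusted over the list alone), with Col8a1 at 11.8 ± 6.67 against 465 ± 11.2 CPM. Myd88 (36.8 ± 0.0488 against 30.0 ± 2.74 CPM) did not pass (edgeR adjusted p 0.43). Without the library block, 23 list genes were higher and 24 lower, against 42 and 42, with 3 higher for MHC class I, 3 for interferon response and 0 for myofibroblastic genes, and 8 lower for the last, 5 for chemokines and cytokines and 0 for receptors and for IL-1 family ligands, also 0 with DESeq2. Adjusted over the list alone, the fit without the block called 8 MHC class I and 7 interferon response genes higher, and 9 myofibroblastic genes, 7 chemokines and cytokines and 1 receptor lower.

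T cell cluster 11 (238 and 161 cells, with Cd4 among its markers) differed from T cell cluster 13 (278 and 50 cells, with Cd8a) in regulatory and IL-1 family genes. Of the T cell states genes, 8 of 16 were higher and 5 lower (8 and 6 adjusted over the list alone) in cluster 11. Foxp3 stood at 175 ± 71.8 against 3.14 ± 4.45 CPM (log2 fold change 4.79 ± 0.37 (SE), edgeR adjusted p 4.2e-12) and the IL-2 receptor gene Il2ra at 834 ± 23.3 against 66.5 ± 20.4 CPM. Foxp3 was not detected in the 50 cells of cluster 13 in set 2, where the limit of 3 counts allows up to 8.99 CPM. Its fold and SE thus rest partly on a value at the floor. Of the TLR and IL-1 family receptors, 5 of 7 were higher and 0 lower, with Il1rl1 at 1070 UMIs in cluster 11 and 3 in cluster 13, and Il1r2 at 159 ± 15.8 against 32.4 ± 9.36 CPM. Nfkbia (684 ± 77.7 against 170 ± 47.9 CPM) and Nfkb1 (2515 ± 12.5 against 882 ± 66.8 CPM) were higher, and the chemokine Ccl5 (463 ± 284 against 1733 ± 1234 CPM) lower. Myd88 (15.9 ± 5.05 against 14.1 ± 1.30 CPM) did not pass. Without the library block, 21 list genes were higher and 4 lower, against 32 and 11, with 3 receptors higher (5 adjusted over the list alone) and 2 T cell states genes lower (4 adjusted over the list alone, and 3 with DESeq2), and Ccl5 was not called (edgeR adjusted p 0.065).

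Tumour epithelial-like cells made up a share 24.1 percentage points higher in set 1. For cells carrying Krt8 and Krt18 at 0.1% or more of non-mitochondrial UMIs, the share differed with no mitochondrial limit by 20.06 points, against 25.7 at 15% or less, which argues against the filter as the whole cause. Such cells rose with mitochondrial content in both sets, from 40.7% at 15% or less to 80.7% above 50% in set 1 and from 15.1% to 39.4% in set 2. In sets 1 and 2 they included 13.5% and 1.24% of kept macrophage or monocyte-like cells and 2.56% and 0.683% of T cell-like cells. Fibroblast-like cells went the other way, at 6.51% and 12.2%. Free keratin RNA may thus add to the share in either set. For set 2 this rests on the fibroblast-like class, which holds the subcluster of 8 and 80 cells led by Krt8, Krt18 and Krt7. There free RNA and that subcluster cannot be told apart. With at least 1000 UMIs per cell the difference was 23.74 points, which argues against droplets under 1000 UMIs as the cause. Cluster 1, tumour epithelial-like and of low UMI count, had a median of 1095 UMIs. Much of it passed that cut, so the test does not cover it. How the tumours were sampled, dissociated or run stays open, and no biological explanation was tested.

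The median of the interferon response genes was lower in set 2 in 3 classes, and Isg15 in all 6. Taking off the empty-droplet profile moved 1 of the named set differences and so decides nothing, and free RNA was tested again, after that, by the highest share of it that markers of other classes allowed in set 1 (2.61 to 7.44% of a class's UMIs, where 23 to 45% would bring a median to 50% of its value). Taken off set 1 alone, it left medians of -1.05 in tumour epithelial-like (-1.11 before), -0.813 in macrophage or monocyte-like (-0.88) and -0.656 in neutrophil-like cells (-0.77), which argues against free RNA as the whole cause in each. Cluster makeup, tested by changing only the clusters' shares of UMIs after a mean within clusters (-0.60) and values per cluster had been seen, gave with profiles of sets 1 and 2 0.0349 and 0.08 in macrophage or monocyte-like cells (class -0.88), and 0.00 and -0.012 in neutrophil-like cells (class -0.77, cluster 3 at -1.61 and cluster 18 at 0.78), which argues against the makeup of these clusters as the cause in both classes. In tumour epithelial-like cells it gave -0.32 and -0.658 of -1.11 (clusters 1, 8 and 10 at -0.41, -0.27 and -1.54), so makeup and a change within cells cannot be told apart there, and no biological explanation was tested.

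Xist, the RNA expressed from the inactive X chromosome, was at 3.04 and 6.54 CPM in tumour epithelial-like cells of sets 1 and 2, against 626 and 680 CPM in fibroblast-like cells. A loss of nuclear RNA was tested on Malat1, which differed by -0.5111 in log2, against -7.19 for Xist and argues against it, while Neat1 was higher by 0.99. Y-linked Ddx3y stood at 0.178 CPM in tumour epithelial-like cells, which argues against an expressed Y chromosome. In cluster 23, led by Cp and Pkhd1, Xist stood at 1359 CPM in set 2. Loss of Xist or of a sex chromosome in the line stays open and was not tested.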
